A study of Mus musculus with 7 samples.

How the data were processed

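RNA-seq counts were analysed for 7 libraries of amygdala cells enriched for astrocytes with ACSA-2 beads, 4 from mice that received the sgRosa guide and 3 from mice that received sgEgfr. The authors deposited whole-number read counts per gene, not normalised, as a table of the series and as 1 file per library. The 7 per-library files held the same counts as the 7 columns of the table. Per the submitters' processing notes, the genome build was mm10 and the tools were STAR 2.7.5c, fastp 0.23.2, FastQC 0.11.9, MultiQC 1.11, featureCounts 2.0.1 and edgeR 3.42.4. The gene annotation, the strand setting of the counting and the treatment of reads that map to several genes were not given in the sources used here, so counts of overlapping genes, antisense genes and near-identical copies are uncertain. Ribosomal protein genes have many processed pseudogenes, and their counts depend on that treatment. Of 35976 gene symbols, 32501 matched a current symbol and 1015 an older symbol of the RefSeq gene table (GRCm38.p6), which also gave the position of Egfr.

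Depth ranged from 5852870 counts in sgRosa 4 to 22579222 in sgEgfr 3, so that 3 counts stood for 0.513 CPM in the former and 0.133 CPM in the latter. Mitochondrially encoded genes took 6.10% to 14.6% of counts. Reads carried no stated molecular identifiers, and limits of this kind cover counting error only.

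Pairs of libraries were compared with a chi-square test over genes with at least 20 counts in the pair. sgRosa 3 and sgRosa 4 lay close to sampling noise, unlike all other pairs, and their counts were summed to 1 sample. The design written before the data were examined had all 7 libraries as separate samples, and that fit is given as an alternative.

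Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), scaled with TMM and tested with glmQLFit and glmQLFTest in edgeR 4.0.16 under R 4.3.3, with the guide as the only term and 3 samples against 3. P-values were adjusted with the Benjamini-Hochberg method over 14936 genes, and genes were called at an adjusted p under 0.05. CPM values of single genes are scaled with TMM, and summed levels of lists are shares of the total count. The common biological coefficient of variation was 0.386.

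The lists were 43 sets of pathway, quality and cell type marker genes, fixed before the data were examined. Each was tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2) and called at an adjusted p under 0.05 over the 43 lists. With limma-voom, camera was run on the voom values and weights. Camera with an estimated correlation and fry were run beside it, and group scores were compared with an exact two-sided permutation test. The score of a list is the mean log2 CPM of its members.

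The genes named were Egfr, called genes by size and p, and, where fewer than 10 per direction passed, the genes with the smallest unadjusted p up to 10 per direction. Up to 4 members with the smallest unadjusted p were named for each list described with examples. This rule was written before the data were examined, and 1 lower gene that it names is not reported here.

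The script was tested on simulated counts for the 14936 genes with the means, depths and spread of the real samples, in 10 runs with 200 genes changed 2-, 4- or 8-fold. Of the genes called, 7.32% were unchanged ones.

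Alternatives written before the data were examined were other scaling factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with and without quality weights, the replicate number as a block, a covariate for other cell types, each library left out in turn, other thresholds, camera with an estimated correlation, and fry. Alternatives added afterwards were the 7 libraries as separate samples, the block on the summed sample, covariates for ependymal, endothelial and heat shock genes, sgRosa 3 and 4 both left out, and sgRosa 2 and sgEgfr 3 both left out. Figures were drawn with matplotlib 3.10.9.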

Results

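The series addressed the part that Egfr, the gene of the epidermal growth factor receptor, plays in astrocytes of the amygdala during chronic stress. Adeno-associated virus delivered Cas9, expressed from the astrocyte promoter GfaABC1D, together with a guide RNA against Egfr (sgEgfr) or against the Rosa locus (sgRosa, the control guide) to the amygdala of male C57BL/6J mice. After at least 2 weeks of expression the mice were restrained on 7 days, conditioned to fear on 1 day and taken through extinction on 3 days. Amygdala tissue was dissociated with papain, and astrocytes were enriched with magnetic beads against ACSA-2, an astrocyte surface antigen. RNA-seq libraries were made from 5 ng of total RNA. The count table held 35976 genes in 7 libraries, 4 from sgRosa mice and 3 from sgEgfr mice, and 24809 genes had at least 1 count. The libraries held 14198048, 18345655, 9890649 and 5852870 counts for sgRosa 1 to 4, and 14983594, 17096879 and 22579222 counts for sgEgfr 1 to 3. The labels did not say that each library came from a separate mouse, so p-values measured the spread between these libraries.

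The counts of sgRosa 3 and sgRosa 4 differed by little more than sampling noise. A chi-square test over 13563 genes gave 1.04 per degree of freedom, where sampling noise alone gives 1, with 5.38% of genes at a p under 0.05 and a chi-square p of 0.000171 over all genes. The other 8 pairs of libraries with the same guide gave 34.3 to 121, and all 20 other pairs gave 14.8 to 158. The counts of sgRosa 3 and 4 were therefore summed to 15743519 and counted as 1 sample, sgRosa 3+4, which left 3 samples per group.

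**Figure D1:**
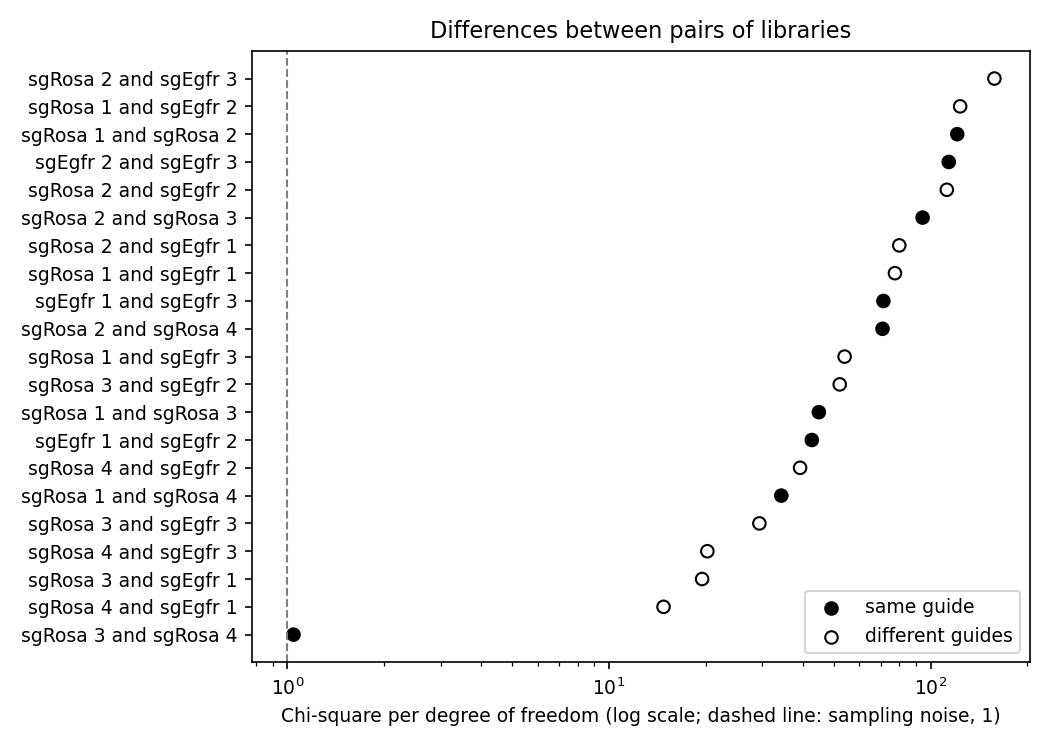
Chi-square per degree of freedom (horizontal axis, log scale) for the counts of each of the 21 pairs of libraries; filled points are pairs with the same guide, open points pairs with different guides, and the dashed line marks sampling noise. The pair sgRosa 3 and sgRosa 4 lies at 1.04, and the other 20 pairs lie between 14.8 and 158.

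Egfr, the targeted gene, was detected in every library, with no difference detected between the guides. It had 188, 55, 109 and 58 counts in sgRosa 1 to 4 and 169, 87 and 184 counts in sgEgfr 1 to 3. Its normalised level was 8.92 ± 5.40 CPM, a count relative to the scaled total of its library, in sgRosa and 8.15 ± 2.51 CPM in sgEgfr (SD, n = 3 each). The log2 fold change was -0.13 (SE 0.54, 95% confidence interval -1.39 to 1.14, edgeR adjusted p = 0.997). Egfr lies on mouse chromosome 11, from 16752203 to 16913907 in GRCm38.p6. The position of the guide in Egfr was not given in the sources used here, and small insertions or deletions made by Cas9 need not lower the mRNA, so the count of Egfr did not test the labels. The direction depended on single libraries: the log2 fold change was -0.55 without sgRosa 2 and 0.27 without sgRosa 1. In fits added after the data were seen, it was 0.79 with the score of the heat shock list as a covariate and -0.67 with that of the endothelial list, without a call.

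No single gene passed the test, and the genes described here were those with the smallest unadjusted p in each direction. Rlbp1, a retinaldehyde-binding protein, was at 12.1 ± 1.97 CPM in sgRosa and 25.9 ± 4.37 CPM in sgEgfr (SD, n = 3), a log2 fold change of 1.09 (SE 0.22). Gfpt2, an enzyme of the hexosamine pathway, had a log2 fold change of 1.18 (SE 0.25), and Tsc22d1, a transcriptional regulator, had 0.72 (SE 0.17). Mapk3, which encodes the kinase ERK1 downstream of EGFR, was at 163 ± 22.6 CPM in sgRosa and 113 ± 4.32 CPM in sgEgfr, a log2 fold change of -0.53 (SE 0.16). Ccr7, a chemokine receptor, Irf4, a transcription factor of lymphocytes, and Lat, a T cell adaptor protein, had log2 fold changes of -2.22, -1.92 and -2.75 at mean levels of 1.22, 1.92 and 1.09 CPM.

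The other higher genes by this ranking were Plk5 (log2 fold change 1.77), Stk32a (1.60), 8430408G22Rik (1.76), Rgcc (0.83), Sgcd (2.45), the Wnt antagonist Frzb (1.75) and Igsf10 (1.71). The other lower genes were Nkain1 (-0.65), the deubiquitinase Usp25 (-0.62), the G protein subunit Gna12 (-0.47), B3galt1 (-0.56) and Gm31152 (-1.93). The edgeR adjusted p was 0.997 for each of these 19 genes. All 19 had CPM ranges that did not overlap between the groups, but they were taken for their small p, and of all genes tested 7.61% had such ranges, where chance gives 10%.

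Of 14936 genes tested with edgeR, 0 were higher and 0 were lower in sgEgfr at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 401 genes, 196 higher and 205 lower, where chance gives 746.8. DESeq2 called 0 genes, with 565 at an unadjusted p under 0.05, limma-voom called 0 with 418, and limma-voom with quality weights called 0 with 793. In simulated counts of the same depth and spread, the test recovered 10.3% of genes changed 2-fold, 56.4% of those changed 4-fold and 80.8% of those changed 8-fold. The real samples gave fewer small p-values than chance does, so these shares may not hold for them.

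**Figure D2:**
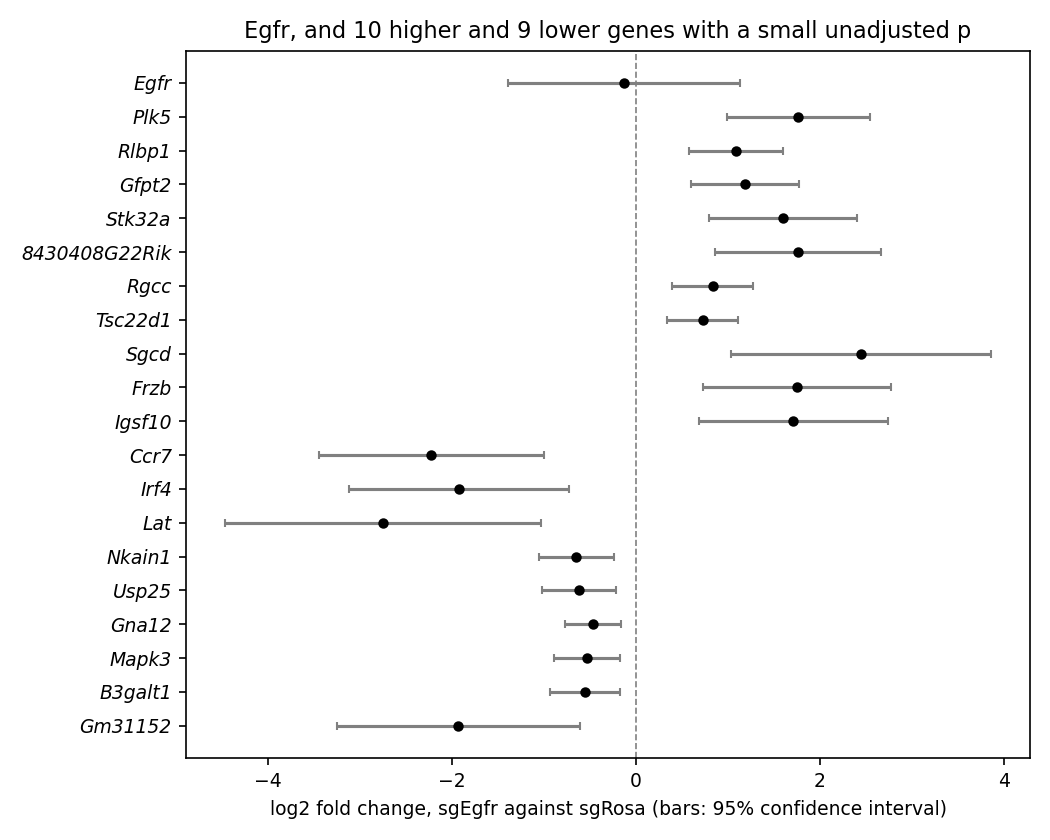
Log2 fold change of sgEgfr against sgRosa (horizontal axis, 3 samples per group) from edgeR for Egfr and for the 10 higher and 9 lower genes named for a small unadjusted p; points are estimates and bars 95% confidence intervals that are not adjusted for the 14936 genes tested. The interval of Egfr runs from -1.39 to 1.14, and none of the genes passed the test after adjustment.

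Genes of the ErbB family and of the ERK pathway, which EGFR activates, were not called as groups with all samples and the guide as the only term. Of 12 measured ErbB receptors and ligands, 5 had positive and 7 negative log2 fold changes, and the list was not called by camera (adjusted p = 0.708). Btc, a ligand of EGFR, had -1.39 (SE 0.56), Nrg1, a ligand of ERBB3 and ERBB4, had 0.70 (SE 0.43), Lrig1, a negative regulator of ErbB receptors, had -0.43 and Erbb4 had -0.20. With the endothelial score as a covariate Btc had 0.10, and without a filter on low counts the mean difference of the list was 0.14, against -0.040 with it. Of 19 measured feedback and target genes of the ERK pathway, 12 were positive, and the list was not called (camera adjusted p = 0.208). Its members with the smallest p went both ways, with log2 fold changes of 0.81 for the cyclin Ccnd1, 0.61 for the ERK phosphatase Dusp6, 0.43 for Etv4 and -0.70 for Myc. No member of either list was called over all genes, and 0 were called adjusted over the list alone. With the heat shock score as a covariate, the ERK list was called higher (mean difference 0.38, camera adjusted p = 0.0201).

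Of the 43 gene lists, camera with a preset correlation of 0.01 called 12, all 12 higher in sgEgfr relative to the other genes. With an estimated correlation it called 0 (adjusted p = 0.742 for each of these 12 lists), and fry called 0 for movement in a shared direction and 0 for change in either direction. Within the 43 lists, 0 genes were called over all genes, and 0 adjusted over the list alone. In fits added after the data were seen, leaving out sgRosa 3 and 4 ended the calls for immediate early genes (camera adjusted p = 0.320), microglia (0.0628), oligodendrocyte precursor (0.163) and fibroblast markers (0.136). Their mean differences were then 0.34, 0.43, 0.38 and 0.37, against 0.53, 0.38, 0.55 and 0.38 with all samples. Leaving out sgRosa 2 and sgEgfr 3 ended the calls for oxidative phosphorylation (camera adjusted p = 0.0972), the unfolded protein response (0.0551) and the matrix list (0.393), whose mean differences were 0.12, 0.23 and 0.24 against 0.16, 0.30 and 0.38. The ependymal score as a covariate ended the call for the matrix list (camera adjusted p = 0.0581) at a mean difference of 0.35.

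Genes that respond to glucocorticoids, the adrenal stress hormones, were among the called lists (camera adjusted p = 3.54e-06; adjusted p = 0.742 with an estimated correlation). Of 23 measured members, 21 had positive log2 fold changes, and the mean over the list was 0.49 higher in sgEgfr on the log2 scale. The 2 negative members were Nr3c1 (-0.37) and Nr3c2 (-0.02). Relative to the mean of the 6 samples, sgRosa 1 lay lowest (-0.56), apart from sgRosa 2 (-0.11) and sgRosa 3+4 (-0.06). The members with the smallest p were Tsc22d1 (0.72, SE 0.17), the cell cycle inhibitor Cdkn1a (1.36, SE 0.35), the lipid droplet protein Plin4 (1.09, SE 0.46) and the transcription factor Zbtb16 (0.44, SE 0.19). The list's score was higher in each sgEgfr sample than in every sgRosa sample (exact two-sided permutation p = 0.1, the smallest that 3 samples against 3 can give). The heat shock list, a sign of handling stress, was also higher in sgEgfr, with a mean difference of 0.33. With its score as a covariate, a fit added after the data were seen, the glucocorticoid call was lost (mean difference 0.25, camera adjusted p = 0.0744), and with the endothelial score as a covariate the mean difference was 0.81.

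Immediate early genes, which neurons and glia switch on after stimulation and also during tissue dissociation, were called higher (mean difference 0.53, camera adjusted p = 0.00362), with 15 of 20 members positive. Fos had a log2 fold change of 1.32 (SE 0.44), Egr1 1.18, Atf3 1.89 and Nr4a1 0.98, and 7 members had an unadjusted edgeR p under 0.05. Atf3 was at 32.5, 55.6 and 218 CPM in sgEgfr 1 to 3, against 27.6 ± 14.6 CPM in sgRosa (SD), so its value leaned on sgEgfr 3. The heat shock list was called higher (mean difference 0.33, camera adjusted p = 0.0212), with 11 of 15 members positive, among them Hspe1 (0.48), Hspb1 (1.61), Hsph1 (0.50) and Dnajb1 (0.81, and -0.11 with the score of this list itself as a covariate). With each library left out, Dnajb1 ranged from 0.088 to 1.15. The unfolded protein response was called higher (mean difference 0.30, camera adjusted p = 0.00623), with 17 of 19 members positive, among them Ppp1r15a (0.68), Atf3 (1.89), Herpud1 (0.44) and Dnajb9 (0.22). These calls had an adjusted p of 0.742 with an estimated correlation. Without sgEgfr 3 the calls were lost for immediate early genes (mean difference 0.29, camera adjusted p = 0.137) and the unfolded protein response (0.20, adjusted p = 0.109), and for heat shock at a mean difference of 0.34 (adjusted p = 0.0748). Without sgRosa 1 they were lost for heat shock (mean difference 0.17, camera adjusted p = 0.358) and the unfolded protein response (0.21, adjusted p = 0.105), and without sgEgfr 2 for heat shock (0.25, adjusted p = 0.111). With the heat shock score as a covariate the calls for immediate early genes (mean difference 0.30, camera adjusted p = 0.203) and the unfolded protein response (0.19, adjusted p = 0.466) were lost. With the endothelial score as a covariate the mean difference of the heat shock list was 0.63.

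Ribosomal protein genes had the smallest camera p of all lists (adjusted p = 4.35e-10; adjusted p = 0.742 with an estimated correlation). All 39 measured members had positive log2 fold changes, with a mean difference of 0.38, and Rps23 had 0.68, Rps14 0.49, Rpl13 0.59 and Rplp0 0.48. Without sgEgfr 2 the mean difference was 0.25, and the list was still called. Nuclear genes of oxidative phosphorylation were called with a smaller mean difference of 0.16 (camera adjusted p = 0.00202; adjusted p = 0.742 with an estimated correlation), with 35 of 39 members positive, among them Uqcrb (0.46), Ndufab1 (0.38), Ndufb3 (0.35) and Atp5h (0.28). The list of extracellular matrix and perineuronal net genes had 19 of 24 members positive and a mean difference of 0.38 (camera adjusted p = 0.0208; adjusted p = 0.742 with an estimated correlation), with Adamts4, a matrix protease, at -0.56, and Tnr (0.81), Tnc (1.36) and Vcan (0.95) positive. With the heat shock score as a covariate the ribosomal call was lost (mean difference 0.13, camera adjusted p = 0.129) and the mean difference of the matrix list was 0.60, and with the endothelial score as a covariate the calls for oxidative phosphorylation (0.12, adjusted p = 0.254) and the matrix list (0.27, adjusted p = 0.468) were lost. The call for oxidative phosphorylation was also lost without sgRosa 2 (mean difference 0.085, camera adjusted p = 0.207) or sgEgfr 2 (0.092, adjusted p = 0.111). That for the matrix list was lost without sgRosa 2 (mean difference 0.29, camera adjusted p = 0.201), sgEgfr 1 (0.26, adjusted p = 0.199) or sgEgfr 3 (0.38, adjusted p = 0.0748).

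Astrocyte gene lists were not called by camera on the filtered log2 CPM values of all samples with the guide as the only term. Of 20 measured astrocyte markers, 13 were positive (camera adjusted p = 0.0717), with log2 fold changes of 0.47 for the zinc transporter Slc39a12, 0.44 for the water channel Aqp4, 0.68 for Gfap and 0.32 for the gap junction protein Gja1. Genes of homeostatic astrocyte functions had 14 of 24 members positive (camera adjusted p = 0.163), among them Slco1c1 (0.62), Aqp4 (0.44), Kcnj16 (0.48) and the glutamine synthetase Glul (-0.34). Pan-reactive astrocyte genes had 7 of 10 members positive (camera adjusted p = 0.0956), with Cp, ceruloplasmin, at 0.54, Hspb1 at 1.61, Gfap at 0.68 and Vim at 1.17 (-0.35 without sgEgfr 3). Hspb1 was at 5.20, 9.62 and 21.4 CPM in sgEgfr 1 to 3 and reached 6.68 CPM in sgRosa 3+4. Gfap was at 143, 177 and 450 CPM in sgRosa 1, 2 and 3+4 and at 486, 536 and 211 CPM in sgEgfr 1 to 3. Both thus overlapped between the groups. The 3 pan-reactive calls that follow are for the whole list. The pan-reactive genes were called higher without a filter on low counts (camera adjusted p = 0.0432), with limma-voom values (0.0451) and with quality weights (0.0391), and the astrocyte markers were called higher with limma-voom values (0.0448). The neurotoxic-type (A1) list had 6 of 11 members positive (camera adjusted p = 0.937) and the neuroprotective-type (A2) list 8 of 8 (camera adjusted p = 0.179). Without sgRosa 2 the mean difference of the astrocyte markers was -0.16 (camera adjusted p = 0.0434) and that of the homeostatic list -0.16 (camera adjusted p = 0.0195), opposite in sign to the values with all samples. Both lists had their lowest score in sgRosa 2, -0.91 and -0.76 relative to the mean of the 6 samples. The astrocyte markers were called higher without sgRosa 1 (camera adjusted p = 0.00853) or sgEgfr 2 (0.0360), and with the heat shock score as a covariate both they (0.000278) and the homeostatic list (0.00587) were called higher. Without sgRosa 3 and 4, the pan-reactive list was called higher (camera adjusted p = 0.0103), and so were the astrocyte and homeostatic lists (0.000467 each).

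Transcripts typical of oligodendrocytes took a larger share of the counts than those typical of astrocytes. Markers of myelinating oligodendrocytes took 11.9% ± 2.72 of all counts, and astrocyte markers 0.979% ± 0.289 (SD, n = 6 samples). The share of astrocyte markers ran from 0.491% in sgRosa 2 to 1.27% in sgRosa 3+4. Mbp, myelin basic protein, alone took 2.23% to 7.43% of the counts of a library. The oligodendrocyte list had 7 of 20 members positive and was not called (camera adjusted p = 0.336), with Gjb1 at -0.54, Mobp at 0.74, Nkx6-2 at -0.58 (0.060 with the endothelial score as a covariate) and Mbp at 0.78. It was called lower without sgRosa 1 (camera adjusted p = 0.0223, mean difference -0.19), without sgEgfr 2 (camera adjusted p = 0.00408, mean difference -0.25) or with the heat shock score as a covariate (camera adjusted p = 2.9e-05, mean difference -0.41). It was called higher without sgRosa 2 and sgEgfr 3 (camera adjusted p = 0.00171, mean difference 0.36).

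Markers of several other cell types were called higher in sgEgfr, beside the gene groups above. Endothelial markers had 16 of 19 members positive and a mean difference of 0.62 (camera adjusted p = 2.52e-06), with Flt1 at 0.80, Ly6a at 0.93, Ly6c1 at 1.30 and Itm2a at 0.70. The groups overlapped, since the endothelial score of sgRosa 1 (0.305) was above those of sgEgfr 1 (0.252) and sgEgfr 3 (0.254), and the mean difference was 0.39 without sgRosa 2 and 1.1 with the heat shock score as a covariate, with the list called in both. Neuron markers had 20 of 20 members positive and a mean difference of 0.47 (camera adjusted p = 2.52e-06), with Vgf at 1.32, Eno2 at 0.60, Elavl4 at 0.56 and Stmn2 at 0.60. Oligodendrocyte precursor markers (11 of 15 positive, mean difference 0.55, camera adjusted p = 0.00712) included Pdgfra (1.33), Tnr (0.81), Neu4 (1.31) and Gpr17 (1.10). Microglia markers (18 of 20 positive, mean difference 0.38, camera adjusted p = 0.0142) included Aif1 (0.85), Ctss (0.81), C1qa (0.67) and Laptm5 (0.51, and -0.12 with the heat shock score as a covariate). With each library left out, Laptm5 ranged from 0.065 to 0.755. Fibroblast and meningeal markers (6 of 10 positive, mean difference 0.38, camera adjusted p = 0.0212) included Pdgfra (1.33), Igf2 (0.95), Lum (0.84) and Dcn (0.46). Each of these calls had an adjusted p of 0.742 with an estimated correlation. Pdgfra belongs to both the precursor and the fibroblast list, and Tnr and Vcan to both the precursor and the matrix list. The calls of these lists are thus not fully separate. The precursor call was lost without sgRosa 1 (mean difference 0.39, camera adjusted p = 0.0785) or sgEgfr 1 (0.34, adjusted p = 0.133), and the microglia call without sgRosa 1 (0.11, adjusted p = 0.659) or sgEgfr 2 (0.0042, adjusted p = 0.770). The fibroblast call was lost without sgEgfr 1 (mean difference 0.36, camera adjusted p = 0.0875) or sgEgfr 2 (0.29, adjusted p = 0.108). Other fits kept these calls at larger mean differences, which were 0.87 for precursor, 0.60 for microglia and 0.60 for fibroblast markers without sgRosa 2, and 0.68 for microglia and 0.70 for fibroblast markers without sgEgfr 3. Without both of these samples they were 0.96, 0.90 and 0.82, and with the endothelial score as a covariate 0.94 for precursor and 0.79 for microglia markers. With the heat shock score as a covariate the precursor call was lost (mean difference 0.38, camera adjusted p = 0.210) and microglia markers were called lower (mean difference -0.28, camera adjusted p = 0.00983), and with the endothelial score as a covariate the fibroblast call was lost at a mean difference of 0.32 (camera adjusted p = 0.237).

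Ependymal markers, genes of the ciliated cells that line the ventricles, had the widest range of mean log2 level between samples of the same group among the 13 cell type lists. Their summed level was 82.3, 56.5 and 552 CPM in sgRosa 1, 2 and 3+4 and 119, 45.2 and 1562 CPM in sgEgfr 1 to 3, a 34.6-fold range. By summed level the range was wider for border macrophage and blood leukocyte markers, 55.0-fold from 14.1 CPM in sgRosa 1 to 775 CPM in sgEgfr 1, a list that holds haemoglobin genes such as Hbb-bs (1.69 and 366 CPM in these samples). The 15 members all had positive log2 fold changes, among them Tekt4 (1.44), Sntn (2.36), Rarres2 (1.20) and Tekt1 (1.32), and the list was not called (camera adjusted p = 0.155). The list was called higher with limma-voom values (camera adjusted p = 0.0183), without sgEgfr 2 (0.00026) and without sgRosa 3 and 4 (0.00108), and lower without sgRosa 2 and sgEgfr 3 (camera adjusted p = 0.000675, mean difference -1.92). Without sgEgfr 3 the log2 fold changes of Sntn, Rarres2 and Tekt1 were -1.91, -0.70 and -0.66. That of Tekt4 ranged from 0.016 to 1.88 with each library left out. The first principal component of the 6 samples, with 54.0% of the variance, had sgEgfr 3 (81.5) and sgRosa 3+4 (44.7) at its positive end and sgRosa 2 (-66.1) and sgEgfr 2 (-48.5) at its negative end. Between them lay sgRosa 1 (-4.88) and sgEgfr 1 (-6.85), so the replicate numbers had the same order in both groups.

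**Figure D3:**
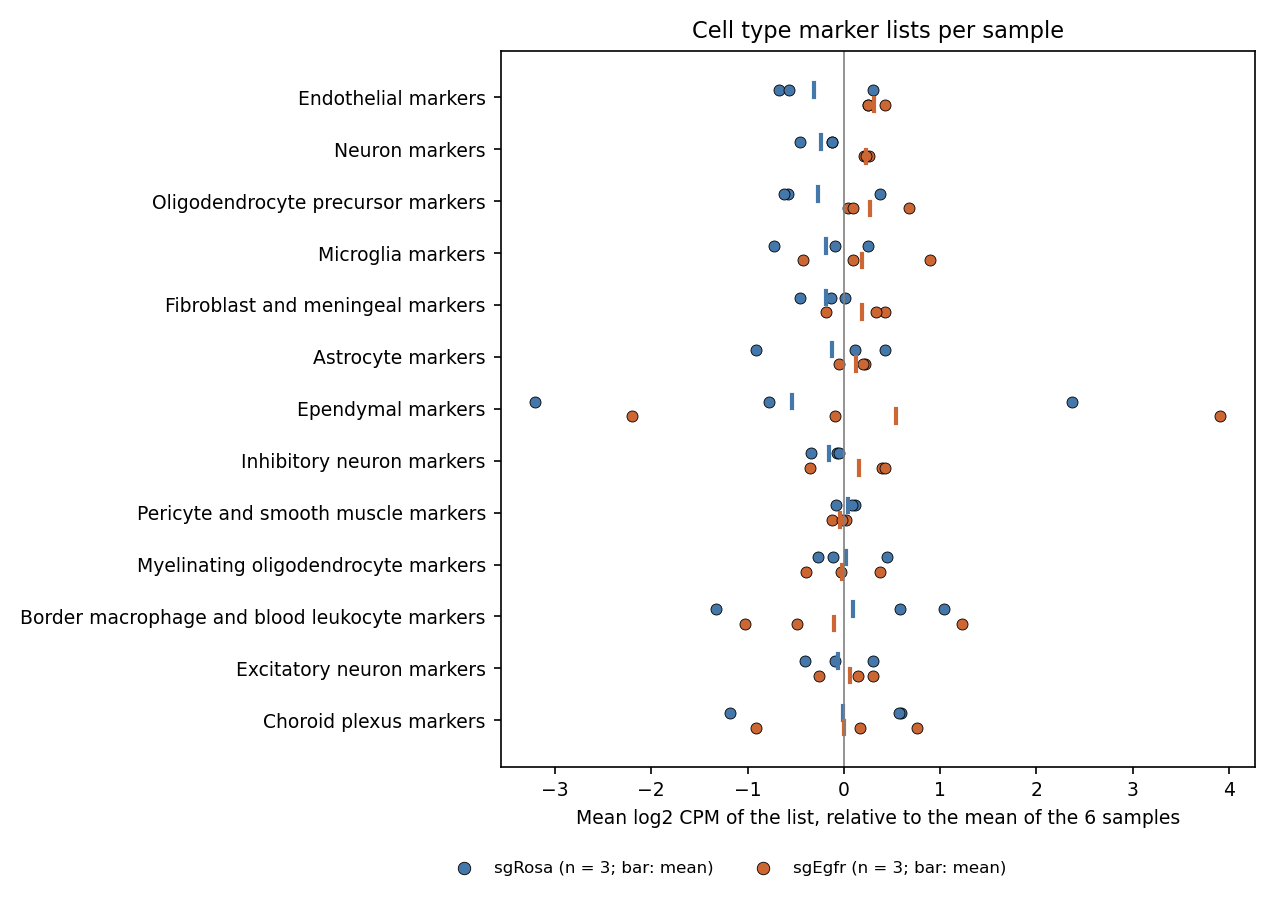
Mean log2 CPM of the 13 cell type marker lists in each sample, relative to the mean of the 6 samples (horizontal axis, log2 units); points are samples, bars are group means, and the groups are sgRosa and sgEgfr with 3 samples each. Ependymal markers spread from -3.21 in sgRosa 2 to 3.91 in sgEgfr 3, while neuron markers lie between 0.21 and 0.26 in sgEgfr and between -0.46 and -0.12 in sgRosa.

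**Figure D4:**
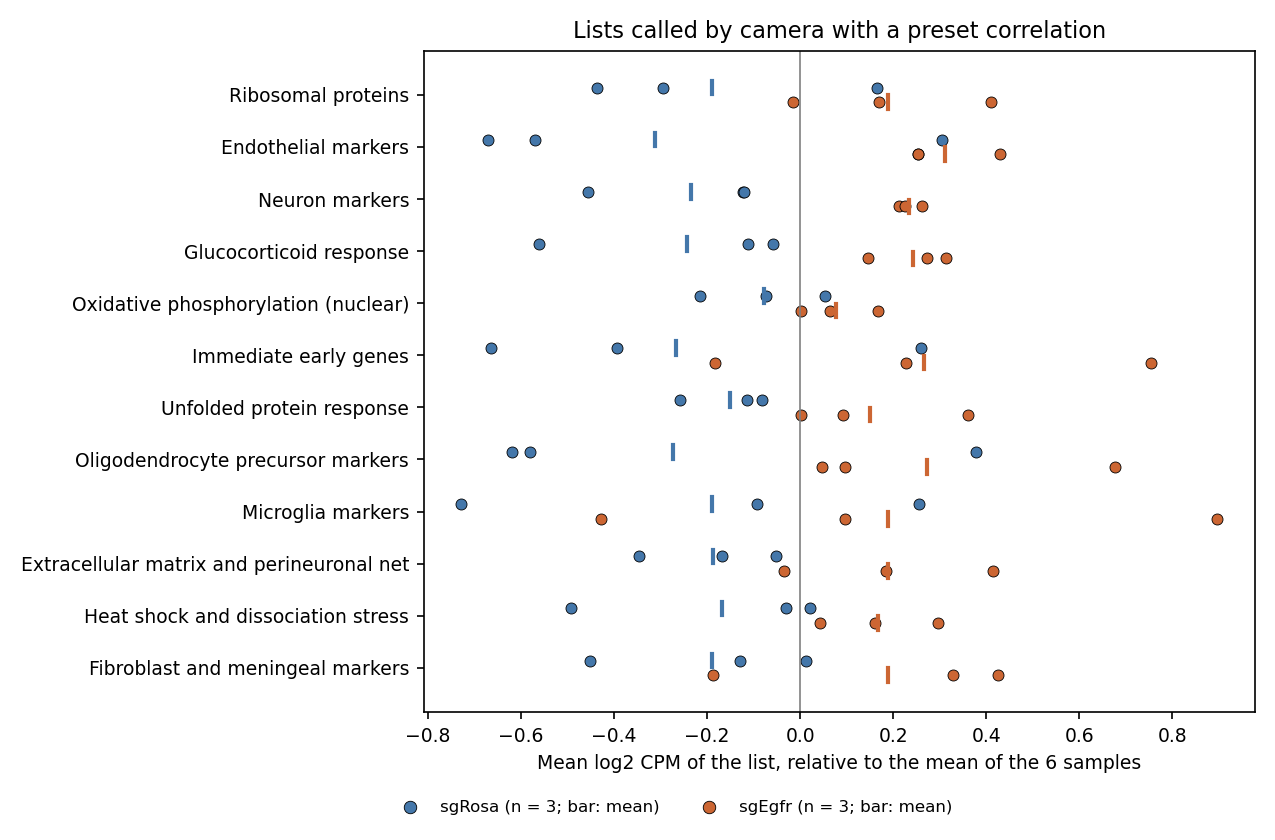
Mean log2 CPM of the 12 gene lists called by camera with a preset correlation in each sample, relative to the mean of the 6 samples (horizontal axis, log2 units); points are samples and bars are group means of 3 samples. The groups do not overlap for 5 lists, among them the glucocorticoid response, with -0.56 to -0.06 in sgRosa and 0.15 to 0.31 in sgEgfr, and they overlap for the others. These 5 are the only such lists of all 43 tested, where chance gives 10%.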

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

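Alternatives with separate or left-out pairs of samples and with ependymal, endothelial or heat shock covariates, and the block on the summed sample, were chosen after the data were seen. All 24 refits of the genes called 0 higher and 0 lower, with 190 to 1337 genes at an unadjusted p under 0.05 and a lowest edgeR, DESeq2 or limma adjusted p between 0.0521 and 0.9999. The 1337 genes and the adjusted p of 0.0521 came from the fit without sgRosa 2 and sgEgfr 3, the samples with the lowest and highest mean log2 level of ependymal markers. The 7 libraries as separate samples gave 0 genes, with 581 at an unadjusted p under 0.05. Same-numbered samples deviated with correlations of -0.11, 0.52 and 0.55, not all above 0.1, so the numbers were not taken to pair the samples, and sgRosa 1 correlated best with sgEgfr 3. Pairing by number is not excluded by this. On the first principal component numbers 1, 2 and 3 lay at -4.88, -66.1 and 44.7 (3+4) in sgRosa. In sgEgfr they lay at -6.85, -48.5 and 81.5, the same order. Number 1 was the middle sample of each group on that component. On the second principal component sgRosa 1 lay lowest of all samples (-45.8), while sgEgfr 1 lay at 18.3. The correlation of -0.11 for number 1 thus cannot be set aside for lack of deviation. Under the replicate block 0 genes and 14 lists were called, ependymal (camera adjusted p = 7.71e-12 with 7 libraries) and pan-reactive astrocyte lists (0.0369) among them, while the fibroblast call was lost with 7 libraries (0.0723) and numbers 1 to 3 (0.0674) but kept with the summed sample (0.0389), and Egfr had a log2 fold change of 0.042 with 7 libraries, 0.045 with numbers 1 to 3 and 0.060 with the summed sample. Egfr was also positive with limma-voom (0.18), with the heat shock covariate (0.79) and without sgRosa 3 and 4 (0.019), and ranged from -0.55 to 0.27 with each library left out. The cause was not tested. The 12 list calls were 0 with an estimated correlation and 0 with fry, whose tests differ in construction, and 10 to 13 with each library left out. Lists were not tested with DESeq2. Of the 12, 2 kept their call in all 23 other refits in which lists were tested (neuron, and endothelial, which has 22 because it was not tested against its own score), and 4 with each library left out (also ribosomal proteins and the glucocorticoid response). All these refits used camera with the preset correlation of 0.01, so they do not test that setting. The estimated correlation was 0.075 for neuron and 0.311 for endothelial markers. Over the 12 lists it ran from 0.045 (matrix list) to 0.745 (microglia). The heat shock covariate gave 12 calls, with 5 of the main ones lost, and the endothelial covariate 8. Upper-quartile scaling gave 12 calls, no filter 13, limma-voom 15 and quality weights 14, and none of these lost a main call. Microglia markers had -0.28, Dnajb1 -0.11 and Laptm5 -0.12 with the heat shock covariate, Btc 0.10 and Nkx6-2 0.060 with the endothelial covariate, and the astrocyte, homeostatic and oligodendrocyte lists -0.027, -0.0088 and 0.20 with the endothelial covariate. The oligodendrocyte list's mean difference was 0.050 with the other-cell-type covariate, 0.078 with the ependymal covariate and 0.10 with quality weights, and that of the ErbB list 0.14 without a filter. Without sgRosa 2 and sgEgfr 3, mean differences were 0.36 for oligodendrocyte, -0.19 for astrocyte, -0.18 for homeostatic and -1.92 for ependymal lists, and Vim had -0.73, Tekt4 -0.38, Sntn -2.50, Rarres2 -1.16 and Tekt1 -1.17. With each library left out, the ranges were -0.16 to 0.36 (astrocyte), -0.16 to 0.26 (homeostatic), -0.25 to 0.17 (oligodendrocyte), -0.61 to 2.44 (ependymal), -0.087 to 0.043 (ErbB), -0.35 to 1.58 (Vim), -1.91 to 2.92 (Sntn), -0.70 to 1.67 (Rarres2) and -0.66 to 1.79 (Tekt1). The cause of these reversals was not tested. Depth limits genes near 1 CPM, such as Lat with 1 to 40 counts per library.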

Other observations

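The camera tests of the lists in this part were planned, while every test of an explanation was chosen, or its bounds were set, after the result it bears on was seen, and so was the list of lymphocyte genes.

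Among the lists not yet described, hypoxia response had 15 of 19 members positive (camera adjusted p = 0.163), complement 11 of 13 (0.185), interferon response 17 of 21 (0.208), NF-kB and inflammatory mediators 13 of 19 (0.213) and mitochondrially encoded transcripts 6 of 9 (0.208). Inhibitory neuron markers had 9 of 13 members positive (camera adjusted p = 0.267) and excitatory neuron markers 2 of 5 (0.656). TGF-beta and BMP signalling (11 of 19), Notch and neural stem cell genes (11 of 20), neurotransmitter receptors of astrocytes (15 of 21), glycolysis (14 of 20), lipid handling (13 of 22) and pericyte markers (6 of 12) had a camera adjusted p of 0.331 each. Circadian clock genes had 7 of 16 members positive and synapse-organising factors 16 of 23 (camera adjusted p = 0.351 each), metallothioneins and oxidative stress 10 of 19 (0.443), border macrophage and blood leukocyte markers 1 of 9 (0.454) and p53 targets 10 of 19 (0.504). Choroid plexus markers (4 of 7, camera adjusted p = 0.674), antigen presentation (10 of 15), cell cycle (8 of 15) and cholesterol synthesis (15 of 23, 0.906 each) were not called. Median and camera direction differed in sign for choroid plexus, antigen presentation, cholesterol synthesis, pericyte, excitatory neuron and neurotoxic-type (A1) lists. Of these, median and mean differed for antigen presentation, pericyte, excitatory neuron and A1 lists, and mean and camera direction for choroid plexus and cholesterol synthesis.

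Of the 10 splits of the 6 samples into 3 and 3, the 10 called 0 genes each, so the real count was 0 and the highest of the others 0. For lists, 6 of the 10 splits called at least as many as the real 12, and the highest other called 15. With 10 splits no share can be under 0.05. The split of sgRosa 1, sgRosa 3+4 and sgEgfr 3 against the rest called 0 genes but had 2251 at an unadjusted edgeR p under 0.05, against 401 for the real split, which points to a structure of the samples other than the guide.

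Ependymal markers, none of which another list holds, set apart other samples, and the split by their order (sgRosa 1, sgRosa 2 and sgEgfr 2 against the rest) had 1642 genes at an unadjusted edgeR p under 0.05. All 15 markers were highest in sgEgfr 3 and next in sgRosa 3+4, which is consistent with ependymal cells in the tissue taken. Depth is argued against as the source, since sgRosa 4, the shallowest library, was 9.57 times above sgRosa 2. The guide held 0.048 of the variance of the score, which argues against it as the whole cause. Under the replicate block with 7 libraries the list was called higher (mean difference 1.06, camera adjusted p = 7.71e-12). The numbers were not taken to pair the samples, so an effect of the guide on top stays open.

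The higher glucocorticoid list had the smallest camera p of the 10 splits (3.29e-07, next 0.000566), but 10 of its 24 genes are in another list. It was taken up because it was called with the real groups, so this first rank is no separate support. With the endothelial score as a covariate its mean difference was 0.8095 (SE 0.0615), far above 0.244, the bound of 0.5 times its main value. The rise leaned on sgRosa 1, which had the highest endothelial score of the sgRosa samples (0.305) and the lowest glucocorticoid score (-0.56). In that sample the list did not follow the endothelial score. With 3 residual degrees of freedom and weight on 1 sample, this fit cannot decide on endothelial content. With the ependymal score the mean difference was 0.464 (SE 0.188), close to the 0.487 of the fit without a covariate. It lay above the bound by little more than 1 SE, with 3 residual degrees of freedom, so this fit cannot decide on ependymal content. With the heat shock score the mean difference was 0.2505 (SE 0.171, against 0.167 without a covariate), and the call was lost (camera adjusted p = 0.0744). Why the call was lost was not tested. Handling stress and an effect of the guide cannot be told apart in these 6 samples. A response to the guide may contribute and was not tested further.

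Lymphocyte signalling genes (Lat, Zap70, Lck, Cd2, Cd5, Cd6, Cd247, Ccr7, Irf4, Ifng), a list made after Lat, Ccr7 and Irf4 were seen, summed to 19.2 ± 5.01 CPM in sgRosa and 5.86 ± 4.25 CPM in sgEgfr (SD, n = 3). The sgEgfr samples had 3.60, 3.22 and 10.8 CPM, a mean of 3.41 without sgEgfr 3, where Zap70 (5.38 CPM) was above its level in sgRosa 3+4 (3.94 CPM). T lymphocytes as the whole source would bring CD3 transcripts, but Cd3e, Cd3d and Cd3g had 23 counts in sgRosa against 273 of Zap70, a ratio of 0.0842. Chance stays open, since the exact two-sided permutation p of 0.1 is the smallest possible and the genes were chosen for the pattern. No other source of these transcripts was tested.

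Single samples also stood apart in single genes, named after their values were seen. Ttr was at 46.2 CPM in sgRosa 1 and at most 4.50 CPM elsewhere, and S100a8 at 4.57 CPM in sgEgfr 1 and at most 0.141 CPM elsewhere.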
